A study of Homo sapiens with 12 samples.

How the data were processed

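Human umbilical vein endothelial cells (HUVEC), primary cells from the lining of the umbilical vein, received a locked nucleic acid (LNA) oligonucleotide against the microRNA miR-663 or a control LNA. They were then kept under oscillatory or laminar shear stress for 24 h. Total RNA was measured on Illumina HumanHT-12 v3 BeadChips, a 1-colour platform with biotin-labelled RNA. The 12 arrays fell into 4 groups of 3 by the LNA and the flow named in the labels. The labels number the arrays of a group but do not say that they came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

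The deposited table held 1 intensity per probe and array for 48794 probes, on a linear scale from 18.0 to 12975. GenomeStudio, with no version, is the only tool named in the submitters' processing notes. The percentiles of the 12 deposited intensity columns coincided almost exactly, with medians between 34.89 and 34.90, as quantile normalization makes them. The method is not given in the sources used here. Values equalized in this way hold no information on the overall amount of RNA. The handling of background is not given in the sources used here, and no detection p-values were used. Since the lowest intensities were above 0 and the median was 34.9, fold changes of dim probes are understated. No pair of arrays shared more than 0.0533% of their values, so no array was counted as a repeat of another.

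The reference table given for gene names (RefSeq genes of assembly GRCh38.p14) holds no Illumina probe identifiers, and the value table does not pair its probes with genes. None of the 48794 probes was therefore given a gene name, and probes are reported by their identifiers. The 26 gene lists and the count of miR-663 seed matches planned before the data were examined need gene names or transcript sequences and were not run. For the same reason, probes of XIST and of Y-linked genes, which were to be left out, could not be set aside. The level of miR-663 itself was not checked, and "knockdown" throughout means the LNA against miR-663 compared with the control LNA.

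Each intensity was increased by 16 and converted to log2. All fold changes are on this log2(value + 16) scale. One limma model (version 3.58.1 in R 4.3.3) was fitted to all 12 arrays with a mean per group, followed by contrasts and moderated variances with an intensity trend. All probes were tested. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 6 comparisons, and every adjusted p below comes from limma unless another test is named. The 6 comparisons were the knockdown under each flow, its average over both flows, the flow effect with each LNA, and the difference of the knockdown effect between flows. "Brighter probes" are the 24397 probes with a mean above the median of all probe means. The knockdown effects under both flows share no arrays, and neither do the flow effects with both LNAs, so their correlations across probes are free of shared controls. Probes are not independent replicates, so no p is given for these correlations. Principal components were computed on the 12199 probes above the 75th percentile of mean log2 intensity.

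The relative flow response of a laminar array is the slope, across brighter probes, of its difference from the mean of the control oscillatory arrays on the difference between the other laminar arrays and the miR-663 LNA oscillatory arrays. No array enters both sides. The groups were compared by a two-sided exact permutation test.

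Named probes were chosen by a rule fixed before the data were examined, applied without its criterion of a gene symbol. Where at least 5 probes were called, these were the largest rises and falls among called probes whose brighter group mean lay above the median and whose arrays did not overlap. Elsewhere they were brighter probes with the smallest p, given as not passing where they did not pass. At most 2 probes are printed per direction and comparison, because the probes carry no names.

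The model was tested on simulated data with the real probe means and the real spread of each flow. In these data, 200 of 48794 probes were changed in the miR-663 LNA oscillatory arrays. The changed probes were drawn from the probes used for the principal components, so recovery of dimmer probes was not tested. Noise was drawn separately for each probe, so differences that the laminar arrays share across probes were not simulated. Of the 50 probes changed 1.5-fold, 70.0% were recovered in the knockdown comparison under oscillatory shear, and of the 50 changed 2-fold all 50 were recovered, with 6 false calls. With the 6 oscillatory arrays alone, 98.0% of the probes changed 1.5-fold were recovered, with 13 false calls. The adjusted threshold is less strict when 200 probes change at once than when few do. These shares therefore do not give the recovery expected where few probes change. The number of arrays limits the precision.

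Alternatives planned before the data were examined were the replicate number as a block, only the arrays compared, no intensity trend, dim probes left out, quantile normalization, a common median, array weights, pseudocounts of 1 and 50, an added 1.5-fold threshold, and each array of a comparison left out in turn. Array weights per flow, a fit without the 2 laminar arrays that stood apart on the second principal component, and leaving out each array outside a comparison, were added after the data were seen. Up to 100 splits of the arrays per comparison were refitted to set each count beside that of other groupings.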

Results

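Gene expression was measured in HUVEC that carried a control LNA or an LNA against miR-663 and were exposed to oscillatory or laminar shear stress for 24 h. The design asked which transcripts respond to the loss of miR-663 under each flow, as a search for its potential targets. Each of the 4 groups held 3 arrays with 48794 probes each. The arrays had a median intensity of 34.9 and a 90th percentile of 247. The probes are reported by identifier because the files do not pair them with genes, so no gene group can be given. Whether the LNA lowered miR-663 was not checked here.

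Flow separated the arrays far more than the LNA did. On the first principal component, which held 62.9% of the variance, the oscillatory arrays lay between -26.90 and -23.16 and the laminar arrays between 12.11 and 32.82. The second component held 16.8% and separated laminar arrays from one another within both LNA groups. Control laminar array 3 lay at -25.20 and miR-663 LNA laminar array 2 at -19.34, and the other laminar arrays lay between 5.23 and 25.11. Oscillatory arrays lay between -4.43 and 0.09 on this axis. The median within-group SD of the brighter probes was 0.0923 and 0.0946 log2 units in the control and miR-663 LNA oscillatory arrays and 0.126 and 0.112 in the corresponding laminar arrays. Within-group variance was larger under laminar flow for 65.4% of the 24397 brighter probes.

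**Figure D1:**
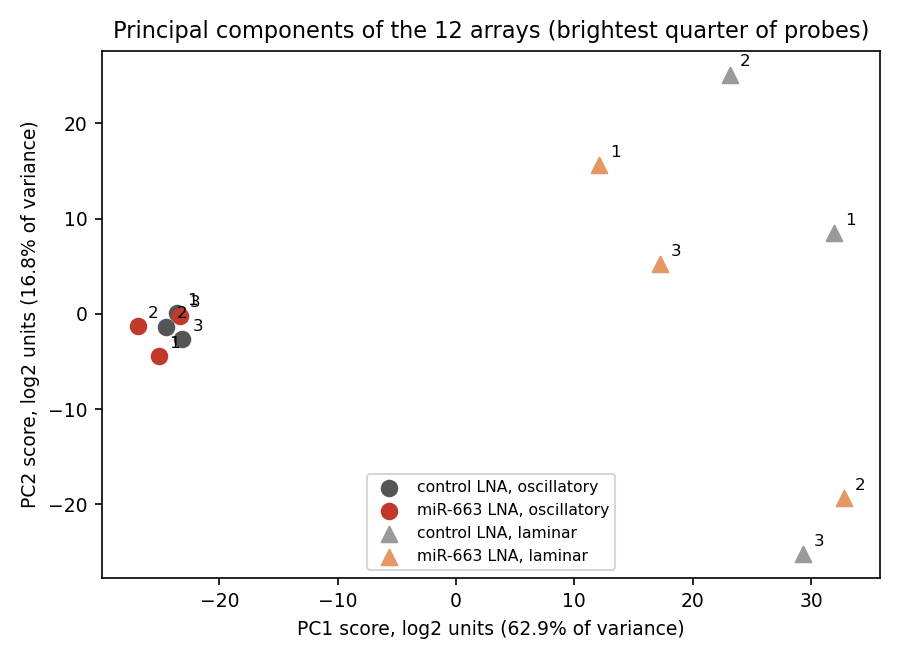
Scores of the 12 arrays on the first 2 principal components of log2(value + 16), in log2 units, with circles for oscillatory and triangles for laminar shear and the replicate number beside each point. The 6 oscillatory arrays lie together at -26.90 to -23.16 on the first component, and the laminar arrays spread from -25.20 to 25.11 on the second.

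With control LNA, oscillatory shear changed 2898 of 48794 probes relative to laminar shear. Of these, 1558 were higher and 1340 lower under oscillatory shear. Leaving out control oscillatory array 2 or 3 lowered the count to 1912 or 1886. The changes reached at least 2-fold for 247 higher and 303 lower probes, and at least 4-fold for 15 higher and 38 lower probes. The median change was 0.61 log2 units among the probes that rose and 0.67 among those that fell. Called probes made up 11.7% of the brighter probes and 0.189% of the dimmer ones, where fold changes are understated. The groups of 3 arrays did not overlap for 28.9% of brighter probes, where chance gives 10%.

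Probe ILMN_1767556 rose under oscillatory shear from 159 ± 110 intensity units under laminar to 2152 ± 142 under oscillatory shear (SD, n = 3), a log2 change of 3.93 ± 0.44 (SE) with an adjusted p of 5.27e-06. Control laminar array 3 held 35.8 units of this probe against 195 and 247 in the others, and without it the log2 change was 3.20. ILMN_1740609 rose from 117 ± 11.1 to 1450 ± 190 (SD, n = 3), a log2 change of 3.45 ± 0.16 (SE) with an adjusted p of 3.38e-11. In the other direction ILMN_1766264 was at 2499 ± 1136 under laminar and 39.4 ± 2.48 under oscillatory shear (SD, n = 3), which is close to the median of all probes and not shown to be above background. Its log2 change of -5.38 ± 0.24 (SE), with an adjusted p of 3.38e-11, therefore depends on the pseudocount, and was -5.82 with 1 and -4.71 with 50 added. ILMN_2314169 was at 2132 ± 176 under laminar and 130 ± 31.9 under oscillatory shear (SD, n = 3), a log2 change of -3.91 ± 0.19 (SE) with an adjusted p of 1.14e-10. All 4 passed in each alternative model and without any 1 of the 12 arrays. Probes that went from below 34.1 units, the median of the probe means, to above 252, their 90th percentile, numbered 0 toward oscillatory and 2 toward laminar shear.

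With miR-663 LNA, oscillatory shear changed 2024 probes relative to laminar shear, 1125 higher and 899 lower. Leaving out miR-663 LNA oscillatory array 1 or 2 lowered the count to 1242 or 1186. At least 2-fold changes were seen for 164 higher and 235 lower probes, and at least 4-fold changes for 17 and 24. ILMN_1767556 and ILMN_1740609 rose here too, with log2 changes of 3.54 ± 0.44 and 3.19 ± 0.16 (SE). ILMN_1766264 was lower under oscillatory shear here too, at 1917 ± 232 under laminar and 40.8 ± 2.76 under oscillatory shear (SD, n = 3), a log2 change of -5.08 ± 0.24 (SE). ILMN_1750324 was at 894 ± 65.1 and 38.9 ± 2.48 (SD, n = 3), with a log2 change of -4.05 ± 0.14 (SE) and an adjusted p of 3.61e-13. The corresponding change of ILMN_1750324 with control LNA was -3.83. The oscillatory levels of both probes lay near the median of all probes, so the sizes of these changes depend on the pseudocount, with -5.52 and -4.49 when 1 was added and -4.43 and -3.41 when 50 was added. The arrays of the 2 flows did not overlap for 27.99% of brighter probes, against 10% by chance.

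The flow effect went the same way with both LNAs. Both comparisons called 1530 probes, and all 1530 changed in the same direction. These were 836 probes higher and 694 lower under oscillatory shear, where independent lists of the same lengths would share 35.9 and 24.7. Of the 1368 probes called with control LNA alone, 94.3% had the same sign with miR-663 LNA. Of the 494 called with miR-663 LNA alone, 91.3% had the same sign with control LNA. The 6 oscillatory arrays lay entirely on one side of the 6 laminar arrays for 3112 brighter probes, or 12.8%, where chance gives 0.216%. Across the 24397 brighter probes the 2 flow effects correlated with a Pearson r of 0.871 and a Spearman rho of 0.649.

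**Figure D2:**
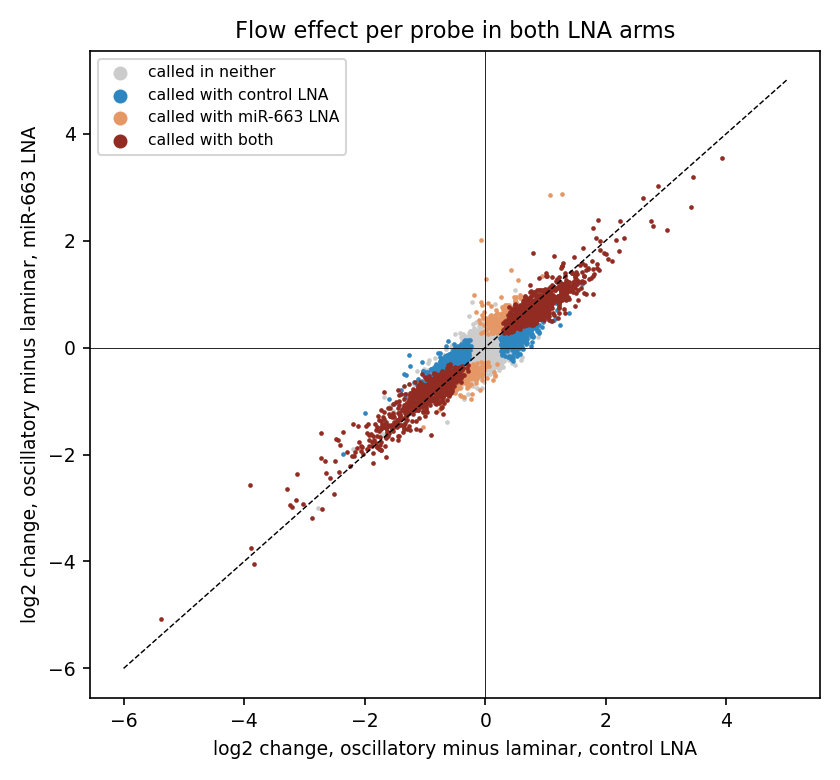
Log2 change between oscillatory and laminar shear for each of the 24397 brighter probes, with control LNA on the horizontal and miR-663 LNA on the vertical axis. Colours mark the comparison in which a probe was called, and the dashed line marks equal changes. The 1530 probes called in both lie in the quadrants of equal sign.

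The size of the flow effect was also compared between the LNAs. Among the 1530 shared probes the median absolute change was 0.81 log2 units with control LNA and 0.75 with miR-663 LNA, and 66.1% had the larger change with control LNA. The relative flow response of the laminar arrays was 0.921 ± 0.114 with control LNA and 0.791 ± 0.186 with miR-663 LNA (SD, n = 3), with a two-sided exact permutation p of 0.4. The difference of -0.130 exceeded the SD of the control arrays in size but not that of the miR-663 LNA arrays. The smallest p that 3 arrays against 3 can give is 0.1. All laminar arrays were set against the control oscillatory arrays in this measure. Its value with miR-663 LNA therefore mixes the knockdown effect with the flow effect. No probe was called by limma for a difference of the knockdown effect between flows, and 2280 had an unadjusted p under 0.05, where 2440 are expected by chance. Without control laminar array 3, 2 probes were called, and without both laminar arrays that stood apart, 18. The brighter probe with the smallest p for this difference was ILMN_2314169. Its flow effect was -3.91 with control LNA and -2.57 with miR-663 LNA, a difference of 1.34 ± 0.27 log2 units (SE) with an adjusted p of 0.989.

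Under oscillatory shear, no probe was called by limma for miR-663 LNA against control LNA. At an unadjusted p under 0.05 there were 2034 probes, 1064 higher and 970 lower, which is below the 2440 expected by chance. This count rests on a spread shared with the laminar arrays. With only the 6 oscillatory arrays, 2888 probes had an unadjusted p under 0.05, which is above that expectation. Array weights gave 2692, array weights per flow 2669, and the fit without the 2 laminar arrays that stood apart 2534. No other alternative exceeded 2222. The 95% interval of the knockdown effect lay within 2-fold either way for 99.7% of the 24397 brighter probes, taken one by one, and its median half-width was 0.22 log2 units. Many brighter probes lay close to the median of 34.9 units, since the 75th percentile was 50.3. Fold changes are understated there, so the interval does not exclude 2-fold changes of these transcripts. The arrays of the 2 LNAs did not overlap for 11.9% of brighter probes. Chance gives 10%, and other splits of the same arrays gave 8.67% to 12.01%, so this is no excess over other groupings. The probe with the smallest p was ILMN_1784540, at 518 ± 34.5 units with control LNA and 270 ± 12.5 with miR-663 LNA (SD, n = 3). Its log2 difference was -0.90 ± 0.14 (SE) and its adjusted p 0.0987. Among brighter probes with a positive difference, ILMN_2374865 had the smallest p, at 88.9 ± 40.8 with control LNA and 242 ± 78.5 with miR-663 LNA (SD, n = 3), a log2 difference of 1.31 ± 0.23 (SE) with an adjusted p of 0.362. Fitted to the 6 oscillatory arrays alone, the comparison called 23 probes, 17 higher and 6 lower with miR-663 LNA, with log2 changes from 0.49 to 2.50 and from -0.90 to -0.45. ILMN_1784540 and ILMN_2374865 were among them, with adjusted p of 0.000104 and 0.00554. In 16 of the 17 higher probes, control array 2 was the highest control array, and in 2 of the 6 lower probes it was the lowest. The miR-663 LNA array 3 was the lowest of its group in 16 of the higher and the highest in 4 of the lower probes. Without 1 array this fit called between 2 and 83 probes, with 44 without control oscillatory array 2 and 83 without miR-663 LNA oscillatory array 3. Another split of the same 6 arrays, which exchanged control array 2 and miR-663 LNA array 3, called 26. All 26 had the same sign in the real split, and 6 were among its 23 calls. The remaining splits called 0.

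Under laminar shear, no probe was called by limma for miR-663 LNA against control LNA either. An unadjusted p under 0.05 was found for 2339 probes, 1162 higher and 1177 lower. The 95% interval lay within 2-fold for 99.7% of brighter probes, with the same limit for probes close to the median intensity. Under both flows the interval uses 1 spread estimated from all 12 arrays, with the same median half-width, so it does not measure the spread of each flow. The median ratio of within-group variance, laminar over oscillatory, was 1.68 among brighter probes. The arrays of the 2 LNAs did not overlap for 8.42% of brighter probes, where other splits of the same arrays gave 6.62% to 17.1%. ILMN_1784540 again had the smallest p, at 468 ± 25.1 units with control LNA and 244 ± 35.1 with miR-663 LNA (SD, n = 3), a log2 difference of -0.91 ± 0.14 (SE) with an adjusted p of 0.0892. ILMN_2167616 was at 1889 ± 83.6 with control LNA and 2562 ± 125 with miR-663 LNA (SD, n = 3), a log2 difference of 0.44 ± 0.10 (SE) with an adjusted p of 0.980. Without control laminar array 3 the comparison called 12 probes, and without both laminar arrays that stood apart it called 230.

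Averaged over both flows, 1 probe fell with miR-663 LNA. This was ILMN_1784540, which fell by 0.90 ± 0.10 log2 units (SE), or 1.87-fold, with an adjusted p of 0.000478. Its difference was nearly equal under both flows, and its flow effects were 0.14 with control LNA and 0.15 with miR-663 LNA, with adjusted p of 0.729 and 0.7497. It passed in each alternative model and without any 1 array. At an unadjusted p under 0.05 there were 2013 probes. The probe with the next smallest adjusted p stood at 0.999. Without both laminar arrays that stood apart, the comparison called 26 probes. Across brighter probes the knockdown effects under the 2 flows did not correlate, with a Pearson r of -0.03 and a Spearman rho of -0.03.

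**Figure D3:**
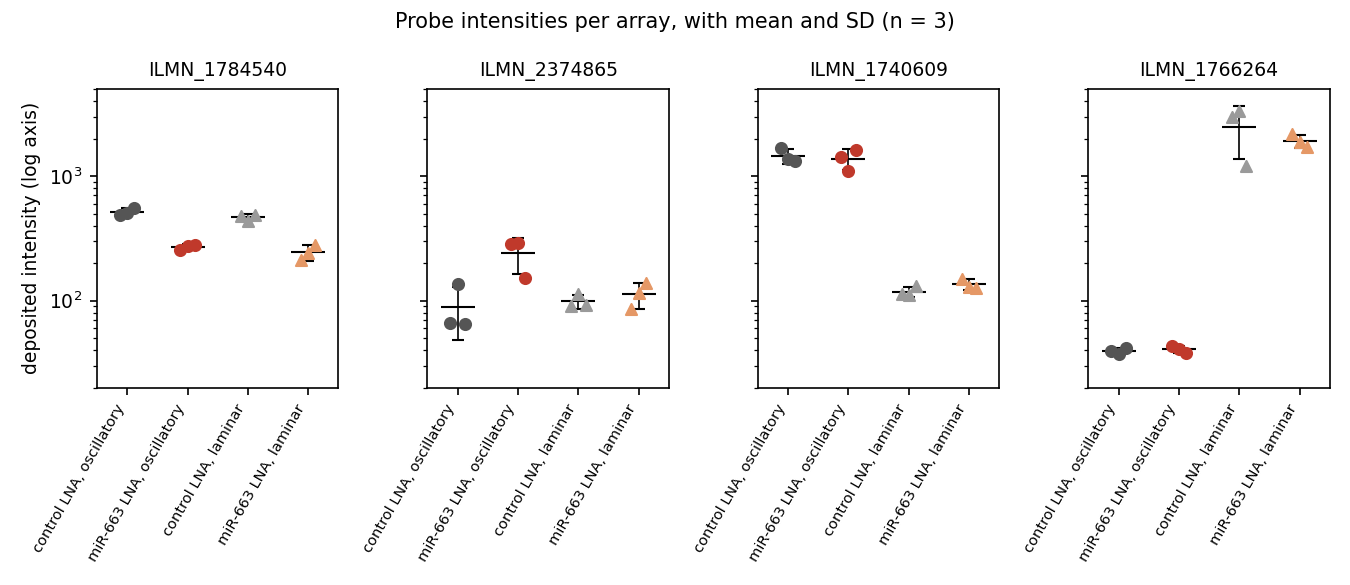
Deposited intensities of 4 probes in the 12 arrays on a log axis, with points for arrays, horizontal lines for group means and bars for SD (n = 3). ILMN_1784540 lies lower with miR-663 LNA under both flows, at 270 and 244 against 518 and 468, while ILMN_1740609 and ILMN_1766264 differ by flow.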

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

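Of the 544 values of named probes recomputed under alternatives, 526 kept their direction and their side of the threshold, 18 moved past it, and 0 changed sign. The 18 belong to 6 of the 23 named probe results. These counts overstate stability, since several alternatives leave the log2 change as it was or nearly so. Among them are the replicate block, no intensity trend, dim probes left out, quantile normalization, a common median and leaving out arrays outside a comparison. Uncalled probes that stayed uncalled are counted too. Array weights per flow, the fit without 2 laminar arrays, and leaving out arrays outside a comparison were chosen after seeing the data.

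Knockdown under oscillatory shear called 0 probes with all 12 arrays, and 1 without the intensity trend, with dim probes left out, with array weights or with array weights per flow. It called 23 with only the arrays compared and 4 without the 2 laminar arrays that stood apart. Leaving out any 1 of the 12 arrays gave 0 to 1 called probes, with 1 without control oscillatory array 2, miR-663 LNA oscillatory array 3 or control laminar array 3. Under laminar shear the count of 0 became 1 without the trend and 1 with dim probes left out, and 230 without the 2 arrays. Leaving out 1 array gave 0 to 12, with 12 only without control laminar array 3. Without the 2 arrays, the averaged comparison called 26 and the difference between flows 18. Leaving out 1 array gave 0 to 2 for the difference, with 2 without control laminar array 3. Leaving out arrays that lie far from their group lowers the spread by construction.

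The flow effect with control LNA called 2898 probes, 1669 with an added 1.5-fold threshold and 4664 without the 2 arrays. Leaving out 1 array gave 1886 to 3541, with 1912 and 1886 without control oscillatory arrays 2 and 3. With miR-663 LNA it called 2024, and 1253 at 1.5-fold. Leaving out 1 array gave 1186 to 2791, with 1242 and 1186 without miR-663 LNA oscillatory arrays 1 and 2. These fits have fewer arrays or a stricter threshold. For the other changes the cause was not tested. The correlation of the knockdown effects ranged from -0.084 to 0.017 without 1 array.

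The replicate numbers were not taken to pair the arrays, since the correlations of 18 same-numbered pairs ran from -0.62 to 0.12 and 5 exceeded 0.1. The best match was the same number in 8 pairs, where chance gives 6. These include all 3 control pairs between flows, at 0.11, 0.04 and 0.11. The replicate block moved the flow counts to 2569 and 1730, left 1 averaged call, and called 0 in the other comparisons.

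Dim probes limit what can be seen, since the median intensity was 34.9 and the lowest value 18.0. The gene lists and the seed matches were not run.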

Other observations

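Tests of the replicate number, of the laminar spread at called probes, of which splits called ILMN_1784540 or followed the laminar arrays, of the order of the oscillatory arrays, of the splits of the oscillatory arrays fitted alone and of those arrays with 1 left out, and the array weights per flow, were chosen only after the result was seen.

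The laminar arrays differed from one another in a way that crossed the LNA groups, and 1 axis held 65.8% of their deviations from the group means. Splitting the 6 laminar arrays otherwise than by LNA called up to 942 probes, where the LNA split called 0, which points to a structure of these samples. A shared culture or day for arrays of one number is argued against by a correlation of -0.62 between same-numbered laminar arrays. A different strength of the flow response, as the main source, is argued against by a correlation of -0.21 between the axis and the flow effect across probes. Along the axis, the relative flow response rose in the miR-663 LNA arrays, at 0.639, 0.735 and 0.998. It did not rise steadily in the control arrays, at 0.827, 1.05 and 0.889, so a partial role stays open. Mixed-in RNA of oscillatory arrays stays open for the 2 laminar arrays with the weakest flow response. Of the 38 probes at least 4-fold higher under laminar shear, 10.5% lay above the control laminar mean in both arrays, between the bounds set beforehand. The design names no groups along this axis, so no biological explanation was tested.

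The 23 probes called for the knockdown on the 6 oscillatory arrays alone were not called with all 12 arrays. A larger spread common to all probes of the laminar arrays is argued against, since array weights per flow brought the count to 1. Such weights are estimated over all probes together, so a larger laminar spread at brighter probes or at these 23 probes stays open. Their SE was larger with all 12 arrays in 23 of 23, and 3 had an unadjusted p of at least 0.05 by limma there. The log2 changes are the same in both fits, so these values largely restate the lost calls. The laminar SD of the 23 probes lay at a median percentile of 69 among the 200 probes closest in mean. A gradient between the oscillatory arrays that crosses the LNA labels stays open, since control array 2 was the highest control array in 94.1% of the 17 probes that rose but the lowest in only 2 of the 6 that fell, while miR-663 LNA array 3 was the lowest of its group in 16 of the 17 and the highest in 4 of the 6, and the count was 44 without it, 83 without miR-663 LNA oscillatory array 3 and 2 to 4 without any other array. The 10 splits of the 6 arrays are too few for a share under 0.05. Of these, 2 called as many probes, with 23 in the real split and 26 in the highest other one. That other split exchanged control array 2 and miR-663 LNA array 3, so it is not separate from the possible gradient. An effect of the knockdown itself remains open.

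The fall of ILMN_1784540 in the averaged comparison does not rest on 1 array, since the highest adjusted p without 1 array was 0.00693. Of 100 splits within each flow, 25 called at least 1 probe, against 1 in the real split and 265 in the highest other one, and 16 had a lowest adjusted p as small, the real split included in both tallies, so by these tallies chance is not excluded. All 24 other splits that called a probe divided the laminar arrays in a way that itself called probes under laminar shear, and 0 of the 66 other splits without such a division called any. The tallies therefore follow the structure of the laminar arrays and do not show what chance gives this probe. ILMN_1784540 was called in 0 of the 99 other splits, but this says nothing about chance. The probe was picked from the real split, with at most 280.3 units in every miR-663 LNA array and at least 439 in every control array. Any other split puts high and low arrays together. A response to the LNA is a hypothesis that these data cannot test further. The level of miR-663 was not checked, and without a gene name nothing can be said on whether the probe belongs to a target.

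For the flow effect, 1 of 10 splits gave as many called probes with control LNA, with 2898 in the real split and 0 in the highest other one, and 1 of 10 with miR-663 LNA, with 2024 and 0. Splits of 3 arrays against 3 are too few for a share under 0.05. For the knockdown under each flow and the difference between flows the real count was 0, which every split reaches by definition (10 of 10, 10 of 10 and 100 of 100), so these tallies say nothing about chance. The highest other counts were 0 under oscillatory shear, 942 under laminar shear and 265 for the difference.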
